A study of Escherichia coli with 9 samples.

How the data were processed

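Total RNA from 1 bioreactor culture was taken at 9 times around the addition of arabinose, from -10 to 60 min. Per the labels' protocols, RNA was extracted with phenol and chloroform, treated with DNase, reverse transcribed and labelled with Cy5 (channel 1) or Cy3 (channel 2). On 8 arrays channel 1 held a sample and channel 2 the sample before it in time, and the closing array set -10 min (channel 1) against 60 min (channel 2). Each sample was thus labelled once with each dye, on different arrays. Scanner software, background correction and normalisation are not given in the sources used here.

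The values the authors deposited are signed fold changes of an array's 2 channels with 1 decimal, as read from the values themselves: 0 values lie between -1 and 1, and 1043 values equal 1 against 1044 that equal -1. A value v was turned into the sign of v times the log2 of its size. The direction, channel 1 over channel 2, was taken from the dyes in the labels. Turning each array's sign in turn, a check planned on the closure of the loop, was void, because all arrays share a component: every array's median signed fold change lies between -2 and -1.3, and arrays correlate across spots at r of 0.37 to 0.84. No dye normalisation or centring is therefore visible in the values. Signal intensities were not used here, so the signal over background of each spot is unknown.

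The slides held 4608 spots, of which 4087 have 1 gene symbol, 0 have several and 521 have none in the platform annotation. Through gene identifiers 4086 spots matched the ASM584v2 gene table, which updated 197 symbols; that table was used for names and for the order of genes on the chromosome, and no coordinates are given. All 9 values were present for 4394 spots, 3957 of them with a gene, or 3908 genes (49 with 2 spots, which were averaged). The arrays held 4472 to 4606 values each, with 252 missing in all. Slide positions were inferred from the spot identifiers, taken as block row, block column, row and column, which gives 16 blocks of 16 rows and 18 columns. The sources used here do not state this layout, and all statements on slide position rest on it.

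The design was fixed before the data were examined. One limma fit over the 9 arrays codes each array as its channel 1 time minus its channel 2 time, which leaves 1 residual degree of freedom per gene, the closure of the loop. Contrasts were 0 against -10 min, early (2, 5 and 10 min) against before (-10 and 0 min), late (20, 30, 45 and 60 min) against before, late against early, and an F test over all times, with Benjamini-Hochberg adjustment over 3908 genes and a threshold of 0.05. In the deposited values the dye bias does not cancel in the closure and sets its spread: the prior SD was 2.78 with infinite prior degrees of freedom. The p values of this fit rest on that closure within 1 culture. Those of the list tests rest on the spread between genes, and those of Fisher's exact test on counts of spots. None measures the spread between cultures.

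Because of that bias, the values and 2-fold counts reported for genes come from a correction chosen after seeing the data, a departure from the design. Within each array a loess curve (limma's loessFit, span 0.4) of the log2 ratio on the spot's mean over all 9 arrays, its loop mean, was fitted on spots with a gene and subtracted. Then the median of the named spots within 3 rows and 3 columns of a spot, itself left out, was subtracted. Spots of a gene were averaged, the loop was solved for levels, and levels were set relative to the mean of -10 and 0 min. The correlation of the loop mean with the late difference moved from 0.67 to -0.05, and with the early difference from 0.73 to 0.05. Medians of print blocks were the alternative to the local step. The SD between duplicate spots was 0.36 with the local step and 0.38 with block medians late, and 0.27 and 0.30 early. The correlation of late differences between adjoining spots in a row was 0.07 and 0.23, but subtracting a local median lowers it by construction, so it does not show which form is better. The correction uses up the closure, so the loop test was not run on corrected values, and it would remove part of a true change shared by all genes of like loop mean. As-deposited values are given relative to the median of all genes, which stood at -0.18 for 0 against -10 min, -0.32 early, -0.23 late and 0.13 for late against early.

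The 28 gene lists were fixed before the data were examined and tested with limma's cameraPR, two-sided, on the moderated t of the deposited values with a preset correlation of 0.01 (lists with at least 4 measured members), adjusted over the lists. The same test was run on the corrected log2 differences, a step added after seeing the data. The version with an estimated correlation was limma's camera on the levels, with time points as samples. It changes the statistic and its degrees of freedom as well as the correlation. A call lost in it cannot be credited to correlation between genes alone. Each list was also set against 10000 random lists of its size, some matched on loop mean. Named genes follow a rule fixed in advance. It takes the arabinose list, a set of envelope and reporter genes, and the 10 largest late changes each way on the same side of the baseline at all late times. It also takes the 5 largest each way in the other comparisons, 4 members of each shifted list and up to 2 of the other lists, among genes past the threshold. As 0 genes passed, the same numbers were taken by size, as the rule provides.

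The steps were tested on simulated data for late against before, with 3957 spots and 200 of them changed. The dye and slide trends added were those that the same correction had estimated. The noise was normal and independent between spots, at each array's median absolute deviation after correction. The rates may therefore be more favourable than in the real data. Median corrected estimates were 1.02 and -0.93 for 2-fold changes and 1.98 and -2.02 for 4-fold changes; 52% and 38% of the 2-fold and 100% of the 4-fold changes up and down were measured as at least 2-fold. Of unchanged spots 0.399% did so after correction and 12.9% as deposited. The loop test called 0 of the 200. A fit with time points as samples called 188 of the 200 but also 243 of 3757 unchanged spots, so its calls are given as an alternative only. In the list test 1 list of 20 genes shifted by 0.5 had an adjusted p of 0.00759, and 0 of 27 unshifted lists were called. As the simulated genes were independent, this does not show the rate of false calls among correlated genes. In the real lists the estimated correlation after correction ran from -0.12 (ATP synthase) to 0.69 (phage shock genes).

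Alternatives covered centring, scaling to one median absolute deviation, robust empirical Bayes, baselines, single times left out, the closing array left out, other list statistics, and other forms of the correction. R 4.3.3 with limma 3.58.1 was used for the statistics and Python 3.11.15 with matplotlib 3.10.9 for the plots.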

Results

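The series followed 1 bioreactor culture of Escherichia coli MG1655 ara through the induction of a bacteriocin release protein. The strain lacks araB and part of araD and cannot use arabinose as a carbon source. Its plasmid carries the release protein of CloDF13, a small lipoprotein that lets proteins leave the cell, with the signal sequence of the lipoprotein Lpp and a histidine tag, under the arabinose-inducible BAD promoter. Alkaline phosphatase (PhoA) and β-lactamase, made from a constitutive promoter, served as reporters of secretion. The culture grew in defined glycerol medium, and arabinose was added at an optical density of around 5. RNA was sampled 10 min ahead of the induction, at the point of induction and 7 times after it, the last at 60 min. Each sample was hybridised with the next in time on 9 arrays with 2 dyes that form a closed loop. The slides held 4608 spots, and 3908 genes had a value on all 9 arrays. The question the labels set is how the samples after induction differ from those before it.

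Each time point is 1 RNA sample from the same culture, so no difference has a check from a second culture. Samples are called before (-10 and 0 min), early (2, 5 and 10 min) and late (20, 30, 45 and 60 min). Levels are log2 values relative to the mean of the 2 samples before, after a correction for dye and slide position that was chosen after the data were examined. The value as deposited, relative to the median of all genes, stands beside a level where it has the other sign or lies over 1.5-fold away. A ± gives the SD over the 3 early or 4 late times. These times share the baseline samples and arrays of the loop, so they are not independent. The SD leaves out errors they have in common and includes change over time, so it is not a measure of precision. For 49 genes printed at 2 spots, the SD between the spots was 0.24 for 0 against -10 min, 0.27 for early, 0.36 for late and 0.34 for late against early. In limma's moderated test of the loop 0 of 3908 genes passed in any of the 5 comparisons, and 0 had an unadjusted p under 0.05. The SE of a log2 difference in that test was 2.62 to 2.95, with its spread set by the dye bias that stays in the closure of the loop, so single genes are given by size and value only. The number of arrays limits the precision as well. A limma fit with time points as samples, which over-called in simulation, called 1 gene early as deposited (leuO) and, after correction, 3 late (rplC, osmB and argA) and 1 late against early (osmB). With no gene under the unadjusted threshold, 0 members of any gene list passed when adjusted over the list alone.

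The 0 min sample, labelled as the point of induction, was compared with the -10 min sample to give the background of the time course. Genes of arabinose uptake were already higher at 0 min. The transporter subunit genes araF and araG stood at 2.75 and 2.51 above -10 min, araJ at 2.02 and the arabinose symporter gene araE at 1.28. All 8 measured members of the arabinose list lay above 0, with a median of 0.98, at percentile 100 of 10000 lists matched on loop mean (limma's cameraPR, adjusted p = 2.83e-19 as deposited and 1.22e-32 after correction). Here and in the comparisons below, the 8 include araB, which the strain lacks, and the partly deleted araD. The sigma E list, genes for outer membrane assembly and repair, had a median of 0.08, with 23 of 34 members above 0. It passed cameraPR (adjusted p = 0.00196 as deposited and 0.0339 after correction), but after correction its median lay at percentile 91.0 of random and 84.0 of matched lists, inside the middle 95%. Its highest members were rseC at 1.04, the sigma factor gene rpoE at 1.01, lptD at 0.98 (in the top 2 rows of the slide) and rseA at 0.89. The Rcs and colanic acid list had a median of -0.15, with 20 of 30 members below 0, at percentile 0.13 of random and 0.10 of matched lists (adjusted p = 0.0117 and 0.0339). Among its members ygdI stood at -0.94, rcsA at -0.64 and wcaJ at -0.62, against 0.80 for gmd. These p values set 1 sample against 1 sample and rest on genes at the preset correlation of 0.01, since none can be estimated from 2 samples, so they describe these samples only.

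Outside the lists, ydcY stood at 1.22 at 0 min. The lowest values were agaR at -1.51, the iron uptake gene efeO at -1.31, grcA at -1.21, ymgD at -1.12 and ycfJ at -1.10. In all, 13 genes were at least 2-fold higher and 6 at least 2-fold lower at 0 min, against 15 and 17 as deposited. A further 8 lists passed on the deposited values alone: heat shock, ribosomal proteins, aerobic respiratory chain, TCA cycle, flagella, arginine, methionine and oxidative stress. Their corrected medians lay between -0.07 and 0.14, and as deposited they were -0.20 for flagella and 0.21 to 0.39 for the others.

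Early after induction, at 2 to 10 min, the arabinose list was the one list called upward in both versions of the test against the mean of -10 and 0 min, but it was not higher than at 0 min. Its median was 0.39 (0.83 as deposited), with 7 of 8 members above 0 (cameraPR adjusted p = 0.0413 as deposited and 0.0250 after correction). With an estimated correlation, in a test that also took time points as samples, the adjusted p was 0.421 as deposited and 0.987 after correction. Its members araF, araG and araJ stood at 0.63 ± 0.82, 0.53 ± 0.77 and 0.47 ± 0.46, and as deposited at 1.46, 1.13 and 1.25. That mean includes the 0 min sample, where the same genes were already high. Against 0 min alone the list did not pass (median 0.00 as deposited and -0.33 after correction, adjusted p = 0.991 and 0.316), and against -10 min alone it did (1.45 and 0.76, adjusted p = 0.000125 and 1.60e-10). The 4 genes at least 2-fold higher at 0 min stood over -10 min at a median of 2.27 at 0 min and 1.03, 1.62 and 2.25 at 2, 5 and 10 min. Without the 10 min sample the list did not pass either (0.289 as deposited and 0.604 after correction). The largest single value belonged to wcaJ, the gene of the enzyme that starts colanic acid synthesis, at 2.95 ± 0.61. Next came ydcR at 1.23 (0.19 as deposited), the exonuclease gene recJ at 1.19, patA at 1.08 (0.48 as deposited) and pyrI of pyrimidine synthesis at 1.06. The lowest were paaY at -2.62 ± 0.39, the regulator gene leuO at -2.50 ± 0.09, fabZ at -1.70 ± 1.38, rsmH at -1.58 ± 1.72 and the capsule activator gene rcsA at -1.38 ± 0.46. The spots of fabZ and rsmH lie in the top 2 rows of the slide, where low values crowd.

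At least 2-fold differences early were found for 10 higher and 40 lower genes. As deposited there were 146 and 377, and without the 5 min or the 2 min sample the total was 24 or 158 in place of 50. Leaving out the outer 2 rows and columns of the slide gave 9 higher and 16 lower. After correction, 25 of 34 sigma E genes lay below 0 (median -0.20, adjusted p = 0.0113) and 15 of 16 Cpx genes (median -0.22, adjusted p = 0.0250). As deposited both medians had the other sign, 0.32 for sigma E and 0.28 for Cpx, and neither list passed (adjusted p = 0.495 for each); with an estimated correlation both had an adjusted p of 0.987 after correction. The corrected calls were lost for sigma E against -10 min alone (0.233) and for Cpx against 0 min alone (0.129), for both without the 10 min sample (0.231) and for Cpx without the 2 min sample (0.0701). Another 8 lists passed as deposited alone: ribosomal proteins, ATP synthase, aerobic respiratory chain, TCA cycle, flagella, methionine, lipoprotein maturation and Sec and Tat export. Their corrected medians lay between -0.14 and 0.15, and as deposited they were -0.46 for flagella and 0.45 to 0.70 for the others. Their adjusted p as deposited with an estimated correlation was 0.410 to 0.480, and 0 of the 28 lists passed early in either version.

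Late after induction, at 20 to 60 min, the arabinose genes, genes of the Cpx and Rcs envelope stress systems and genes for histidine synthesis and ribosomal proteins were higher, and arginine synthesis genes were lower. These 6 of the 28 lists shifted the same way in the cameraPR test as deposited and after correction, and with an estimated correlation 0 of the 28 passed in either version. Without the 60 min sample the Rcs and arginine lists did not pass as deposited (adjusted p = 0.203 and 0.0746), while after correction the 6 lists passed with each late sample left out in turn. With ranks in place of values the Cpx list did not pass after correction (adjusted p = 0.0907) and the Rcs list did not pass as deposited (0.179), nor did Rcs as deposited against -10 min alone (0.0811). The arabinose list rose by a median of 1.40, with 7 of 8 members above 0 and 5 at least 2-fold higher (adjusted p = 3.58e-08 as deposited and 1.32e-12 after correction). The genes araE, araF, araJ and araG stood at 1.93 ± 0.36, 1.93 ± 0.42, 1.92 ± 0.65 and 1.55 ± 0.34, with 2.76, 2.66 and 2.38 as deposited for the last 3. That baseline includes the 0 min sample. Against -10 min alone the same genes stood at 2.58, 3.30, 2.94 and 2.81, or 3.24, 4.12, 3.89 and 3.70 as deposited, and the list's median was 1.97. The partly deleted araD stood at 1.25, araA, in the top 2 rows of the slide, at 0.66 and the regulator gene araC at -0.33 (0.57 as deposited). The deleted araB gave 0.55, or -0.60 as deposited, from one of the lowest loop means of the named genes (-1.92). With an estimated correlation the adjusted p of the arabinose list was 0.332 as deposited and 0.481 after correction.

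The Cpx list holds genes that answer misfolded proteins in the envelope, and it rose by a median of 0.26 (0.74 as deposited), with a mean of 0.45. Of its 16 measured members 10 lay above 0 and 4 were at least 2-fold higher (adjusted p = 0.000376 as deposited and 0.000254 after correction). These 4 were dgcZ, a diguanylate cyclase gene, at 2.39 ± 1.82, yebE at 1.97 ± 1.11, the periplasmic chaperone gene spy at 1.20 ± 0.92 and the periplasmic protease gene degP at 1.13 ± 0.74. Without the 60 min or the 45 min sample the median of the list was 0.06 or 0.08, without the 20 min sample it was 0.48, and among the 13 members away from the slide edge, with a narrower spatial window, it was -0.03. The spot of degP lies in the top 2 rows. The Rcs and colanic acid list rose by 0.38, with 24 of 30 members above 0 and 5 at least 2-fold higher (adjusted p = 0.0148 and 2.01e-08), but as deposited its median lay at percentile 86.7 of random lists, inside the middle 95%. Its leading members were the lysozyme inhibitor gene ivy at 2.07 ± 0.25, the lipoprotein gene osmB at 1.95 ± 0.30 (2.89 as deposited), bdm at 1.70 ± 1.04 (2.41 as deposited) and wcaJ at 1.67 ± 0.66. The course of wcaJ ran against that of the list. It stood at 3.58 at 2 min and fell from 2.49 (3.09 as deposited) at 20 min to 1.03 at 60 min. Over the same late times the list's median went from -0.12 to 0.65. With an estimated correlation the adjusted p was 0.332 as deposited and 0.650 after correction for Cpx, and 0.661 and 0.481 for Rcs.

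**Figure D1:**
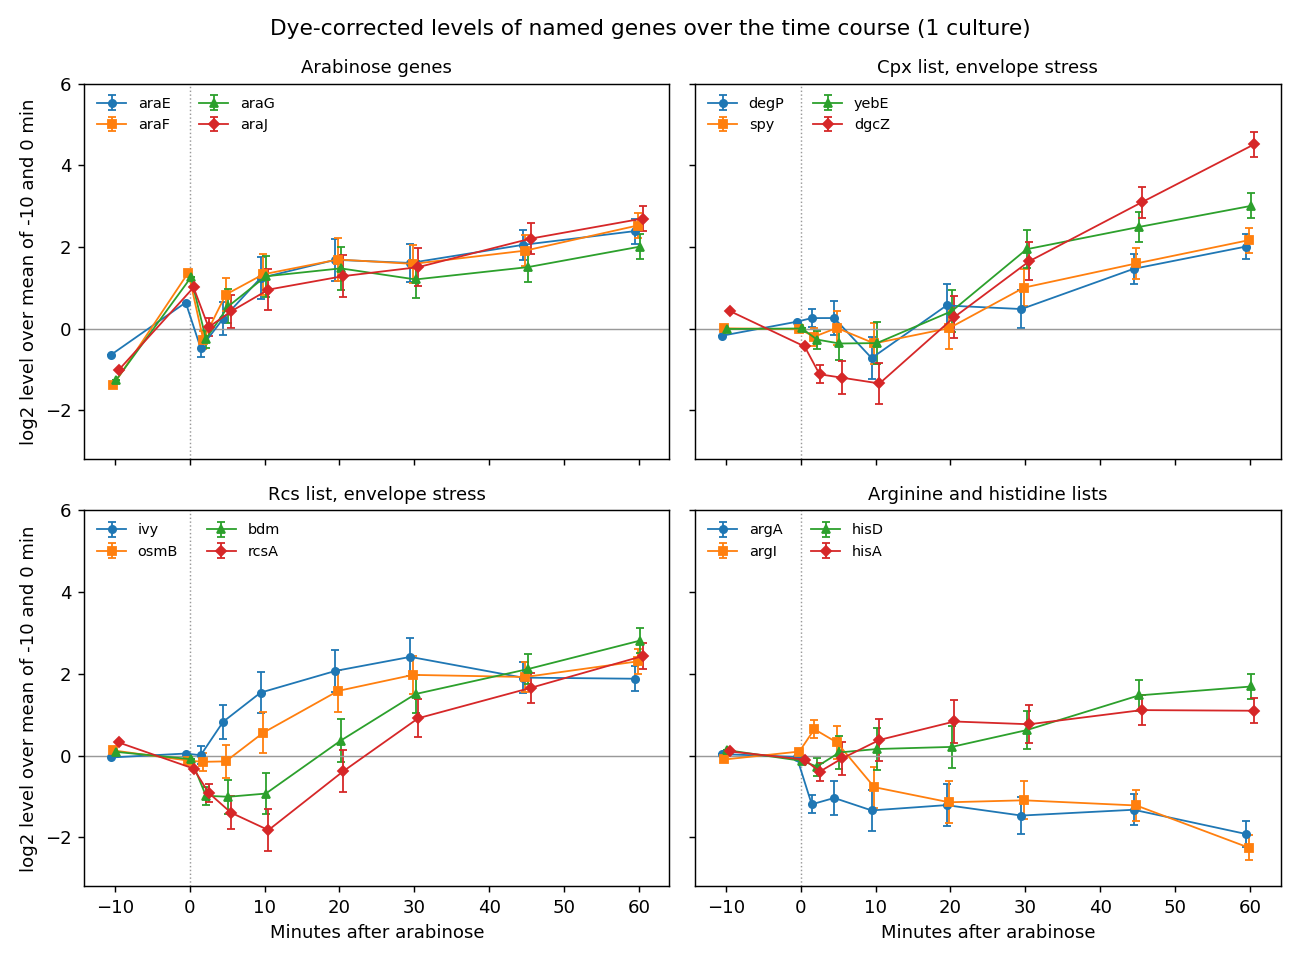
Dye-corrected log2 levels of 16 named genes against minutes after arabinose, relative to the mean of -10 and 0 min, with points moved slightly sideways for legibility; bars give the SD between duplicate spots of 49 genes at each time from 2 min (0.22 to 0.52). At 60 min dgcZ stood at 4.51 and argA at -1.92, and araF was 2.75 higher at 0 than at -10 min.

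Ribosomal protein genes rose by a median of 0.25 (1.09 as deposited), with 43 of 54 above 0 and 2 at least 2-fold higher (adjusted p = 6.91e-17 and 0.000159). The highest were rplC at 1.30 ± 0.07 (2.33 as deposited), rplY at 1.08 ± 0.41, rplB at 0.88 ± 0.40 and rplW at 0.79 ± 0.40 (1.79 as deposited). Histidine synthesis genes rose by 0.53 (1.02 as deposited), with 7 of 8 above 0 and 0 past 2-fold (adjusted p = 0.000442 and 0.00230). Of these, hisD stood at 1.00 ± 0.70, hisA at 0.95 ± 0.18, hisB at 0.56 and hisH at 0.55, with 1.90 and 1.65 as deposited for the first pair. Arginine synthesis genes fell by 0.88 (a median of -0.74 as deposited), with 10 of 11 below 0 and 2 at least 2-fold lower (adjusted p = 0.00235 and 7.49e-08). The lowest were argA, of the first step of the pathway, at -1.48 ± 0.31 (-2.23 as deposited), argI at -1.43 ± 0.55, carA at -0.94 ± 1.50 and argD at -0.91 ± 0.28. With an estimated correlation each of these 3 lists had an adjusted p of 0.332 as deposited and 0.481 after correction.

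A further 4 groups passed as deposited but not after correction, and their corrected medians were small. All 4 were shifted upward as deposited. These calls were lost with scaled arrays for ATP synthase, lipoprotein maturation and export (adjusted p = 0.783, 0.899 and 0.774), against 0 min alone for the last 2 (0.0809 and 0.0524) and with ranks for the phage shock genes (0.0678), whose deposited median lay at percentile 89.0 of random lists, inside the middle 95%. The median of the phage shock genes was 0.41 as deposited and 0.14 after correction (adjusted p = 0.0161 and 0.106), and that of ATP synthase 0.68 and 0.10 (0.0114 and 0.451). For lipoprotein maturation with Tol-Pal it was 0.63 as deposited but -0.11 after correction (0.0260 and 0.796), and for Sec and Tat export 0.58 but -0.04 (0.0161 and 0.706). Without the 45 min or the 60 min sample the phage shock genes did not pass as deposited either (0.0517 and 0.203), with corrected medians of 0.09 and -0.11. After correction they passed without the 20 min or the 30 min sample (0.00153 and 0.0152, medians 0.53 and 0.28). The corrected median of Sec and Tat export was 0.02 without the 20 min sample and -0.14 without the 45 min sample. Among their members pspB stood at 1.38 ± 0.70 (2.15 as deposited), pspA at 0.69 ± 0.83 (1.67 as deposited), atpI at 0.53, nlpE at 0.59 (in the top 2 rows), secB at -0.70 and secY at 0.57 (1.64 as deposited). With an estimated correlation their adjusted p was 0.332 as deposited for ATP synthase, lipoprotein maturation and export and 0.520 for the phage shock genes.

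The heat shock list, chaperone and protease genes under sigma 32, lay below 0 after correction for 17 of 19 members, with a median of -0.57 (adjusted p = 2.32e-05), but did not pass as deposited (median -0.04, adjusted p = 0.855). Its corrected median was -0.96 at 20 min, -0.70 at 30 min and -0.68 at 45 min, but -0.04 at 60 min, or -0.30, -0.05, -0.02 and 0.21 as deposited. The small chaperone gene ibpB stood at -1.11 ± 0.81 and clpX, in the top 2 rows of the slide, at -1.07 ± 0.76. Aerobic respiratory chain genes had a corrected median of -0.41 (adjusted p = 0.00112, 0.612 as deposited), with nuoA at -0.97 (-0.27 as deposited) and nuoI at -0.96. The TCA cycle had -0.15 (0.0290, 0.0748 as deposited), with gltA at -0.70 (-0.01 as deposited). Its 1 member at least 2-fold lower, lpd, has its spot in the top 2 rows of the slide, and the list was not tested without it. Methionine synthesis had -0.36 (0.00994, 0.513 as deposited), with metE at -1.30 and metA at -1.09 (-0.34 as deposited), and flagella and chemotaxis had 0.23 (0.0290, 0.0949 as deposited), with fliD at 1.14 and flgA at 0.88 (0.15 as deposited). The as-deposited direction was the opposite for these last 4 lists: their medians were 0.01, 0.49, 0.43 and -0.21. With scaled arrays, though, the deposited values called the respiratory chain downward (adjusted p = 0.000747). The corrected calls held in 5 of 10 corrected settings with the preset correlation for the TCA cycle and in 6 of 10 for flagella. The TCA cycle did not pass without the 45 min or the 60 min sample (adjusted p = 0.0886 and 0.0807), with ranks (0.0986), with block medians (0.242) or against -10 min alone (0.133), and its corrected median lay at percentile 16.4 of random and 21.7 of matched lists, inside the middle 95%. Flagella did not pass without the 20 min or the 30 min sample (0.0778 and 0.0701), with block medians (0.0620) or with a 2-spot window (0.112). As deposited the TCA cycle passed upward without the 60 min sample (0.0445), with ranks (0.0192) and against -10 min alone (0.0127), flagella passed downward against -10 min alone (0.0245), and heat shock passed downward with scaled arrays (0.0484). The corrected median of the TCA cycle was -0.33 without 20 min and -0.10 without 45 min, and that of the respiratory chain -0.27 without 60 min. With an estimated correlation the adjusted p after correction was 0.564 for heat shock, 0.650 for the TCA cycle and 0.481 for the other 3.

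The other 13 lists did not pass as deposited (adjusted p from 0.256 to 0.839) or after correction (0.106 to 0.863) in the main settings. After correction acid resistance passed downward without the 20 min sample (0.0239), with ranks (0.0498), with block medians (0.0215) and with a 2-spot window (0.0388), and its corrected median lay at percentile 1.13 of random and 2.05 of matched lists. That of leucine, isoleucine and valine synthesis lay at 0.69 and 0.91, and both are outside the middle 95%. As deposited sigma E passed upward against -10 min alone (0.0429), and the leucine list passed downward with scaled arrays (0.0271). Their corrected medians were -0.02 for sigma E, -0.09 for RpoS general stress, -0.36 for acid resistance, -0.12 for SOS, -0.08 for the phosphate regulon, -0.15 for glycerol genes and 0.06 for other sugar genes. The rest stood at -0.36 for leucine, isoleucine and valine synthesis, -0.06 for iron uptake, -0.06 for oxidative stress, -0.18 for porins, 0.02 for anaerobic metabolism and -0.06 for peptidoglycan synthesis. As deposited the median had the other sign for sigma E (0.29), RpoS (0.16), glycerol genes (0.31), oxidative stress (0.32), porins (0.28), anaerobic metabolism (-0.12) and peptidoglycan synthesis (0.07). Galactose genes led the other sugar genes, with galT at 1.47 ± 0.16 (2.48 as deposited) and the permease gene galP at 1.39 ± 0.30 (2.15 as deposited). Single members of further lists were lptD at -1.37 (-0.52 as deposited, in the top 2 rows), slp at 0.87, hdeA at -0.85, dps at 0.65 (1.41 as deposited), ilvN at -0.81, sufD at -0.81, nmpC at -1.24 (-0.28 as deposited) and dacA at -1.12 (-0.46 as deposited, in the top 2 rows).

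**Figure D2:**
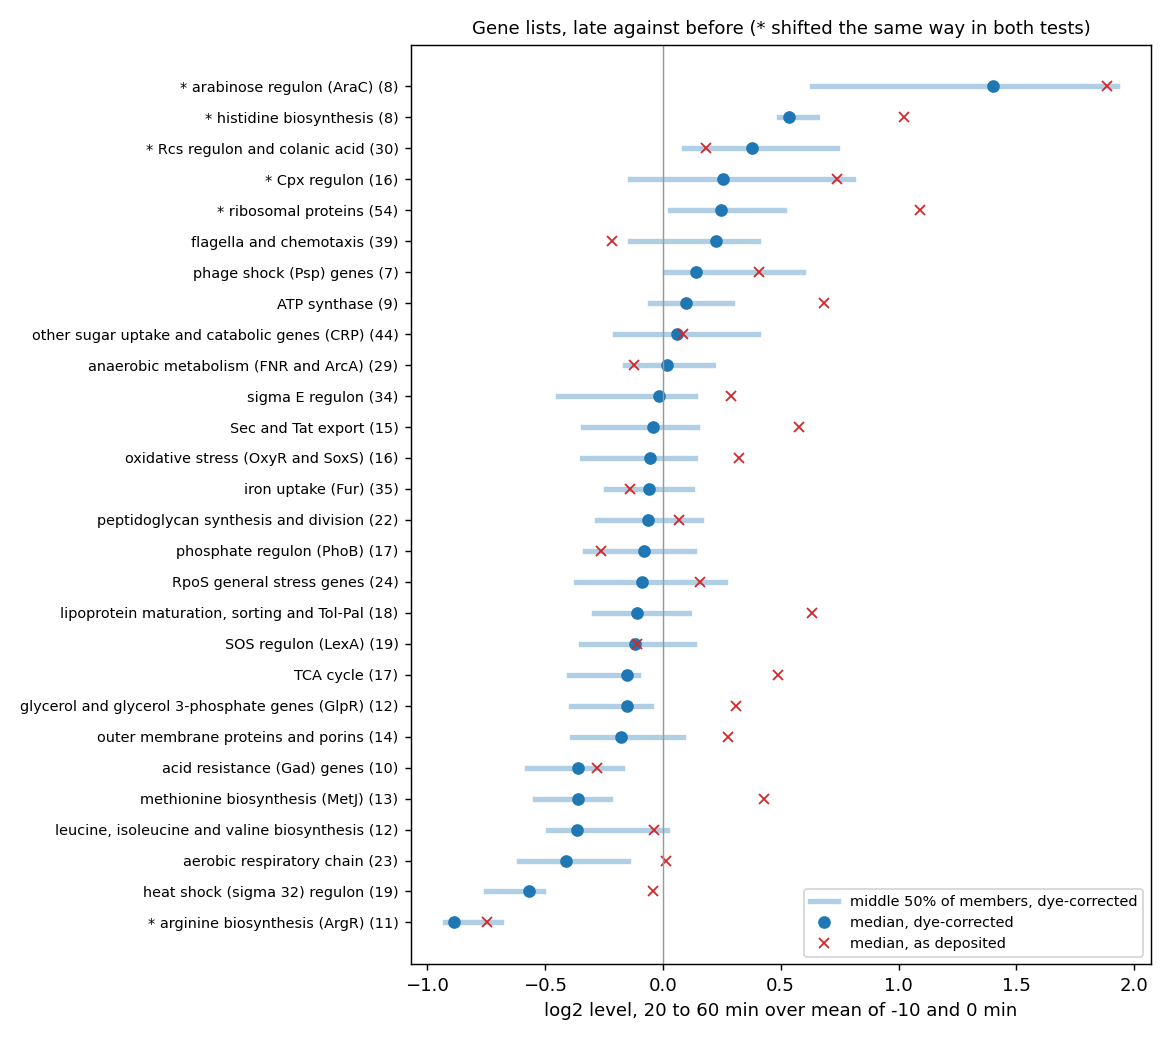
Median log2 level of each of the 28 gene lists over the late times, relative to the mean of -10 and 0 min (horizontal axis), dye-corrected (circles, with bars over the middle 50% of members) and as deposited (crosses); the number of measured members is in brackets and a star marks lists shifted the same way in both tests. The arabinose list stood at 1.40 and arginine synthesis at -0.88 after correction, and ribosomal proteins at 0.25 against 1.09 as deposited.

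Among genes fixed in advance for the envelope and the reporters, phoA stood at -0.41 ± 0.04 late (0.48 as deposited); whether its spot also measures a plasmid copy could not be checked. The lipoprotein gene lpp stood at 0.01 ± 0.19, the phospholipase gene pldA at -0.13 ± 0.19, rpoE at -0.55 ± 0.49 and rpoH at 0.14 ± 0.26. The value of rpoE depends on the baseline, as rpoE itself stood at -0.51 at -10 min and at 0.51 at 0 min. Its late levels ran from -1.19 at 20 min to 0.00 at 60 min, so a late fall below -10 min is not shown. The porin gene ompF stood at -0.96 ± 0.35 (-0.35 as deposited), ompC at -0.35 ± 0.15 (0.56 as deposited) and ompA at 0.08 ± 0.57 (1.33 as deposited). The glycerol genes glpK and glpF stood at -0.06 and -0.24, and at 0.77 and 0.56 as deposited. The gene cpxP was not among those with 9 values.

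The highest late values of all genes were ycfJ at 2.72 ± 1.22 (3.40 as deposited), dgcZ, yaiY at 2.22 ± 1.52 and ivy, followed by yebE, osmB, araE, araF, araJ and bdm. The lowest were secM at -2.49 ± 1.15, the dihydrolipoyl dehydrogenase gene lpd at -2.22 ± 0.75, apaG at -1.99 ± 0.58 (-1.31 as deposited), aroL at -1.82 ± 0.95 and yjcH at -1.81 ± 0.60. Next were yadV at -1.72 ± 0.27, frmA at -1.67 ± 0.83 (-0.92 as deposited), yedE at -1.66 ± 0.12, insL1 at -1.56 ± 0.73 and leuO at -1.56 ± 0.45. Of these 10 lowest genes 7 have their spot in the top 2 rows of the slide, which hold 2.50% of all spots, and yjcH, yedE and leuO do not. Late, 52 genes were at least 2-fold higher and 52 at least 2-fold lower, or 2.66% of the 3908. Leaving out the outer 2 rows and columns of the slide gave 41 and 27, leaving out the array that closes the loop gave 45 and 83, and the deposited values gave 278 and 325. The closing array was left out only after the correction, which had used all 9 arrays, so its count is no independent check.

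The late samples were set against the early ones to show what differed within the time after induction. The largest differences upward were in ycfJ at 3.75, dgcZ at 3.60, yaiY at 3.37, bdm at 2.68 and rcsA at 2.53. Downward they were in the pyrimidine genes pyrI at -1.90 and pyrB at -1.73, in yjcH at -1.86, in argI at -1.49 and in recJ at -1.46. In this comparison 57 genes were at least 2-fold higher and 32 lower. Without the 10 min or the 20 min sample the total was 174 or 159 in place of 89, and as deposited it was 132 and 81.

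Time by time, the number of genes at least 2-fold from the level before was, after correction, lowest at 2 min (5 higher and 16 lower) and highest at 20 min (173 and 166), or 8.68% of the 3908. At 5 min there were 34 and 138, at 10 min 110 and 162, at 30 min 92 and 102, at 45 min 71 and 61, and at 60 min 79 and 69. As deposited the total was highest at 10 min instead (1607), with 66 at 2 min, 765 at 5 min, 1271 at 20 min, 1149 at 30 min, 678 at 45 min and 209 at 60 min. The SD between duplicate spots followed a like course, from 0.22 at 2 min to 0.52 at 20 min and 0.31 at 60 min. Times farther from -10 and 0 min along the loop are joined to them by more arrays. Median levels of the Rcs list were -0.12 at 20 min, 0.32 at 30 min, 0.51 at 45 min and 0.65 at 60 min, those of the Cpx list -0.17 (0.50 as deposited), 0.16 (0.90 as deposited), 0.49 and 0.69, and those of the arginine list -0.64, -0.75, -0.81 and -1.32.

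**Figure D3:**
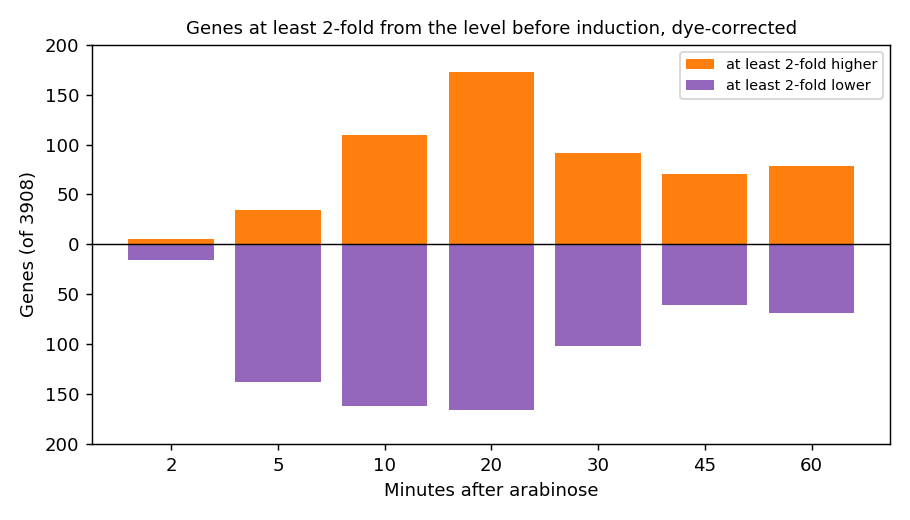
Number of genes (of 3908) at least 2-fold higher (bars upward) or lower (bars downward) than the mean of -10 and 0 min at each time after arabinose, dye-corrected. The count was 173 and 166 at 20 min and 79 and 69 at 60 min. As deposited, not drawn, the total was highest at 10 min (1607, against 1271 at 20 min).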

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

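All tests of the arabinose genes at 0 min and of the slide edge were chosen after these results were seen. Of 73 groups of values checked for one that stands apart, 4 held such a value, and chance alone gives about 1 in 20. The array of -10 over 60 min stood apart in missing values, with 136 against 2 to 40 on the other arrays. The array of 5 over 2 min stood apart in its lowest signed fold change, -122.7 against -37.5 to -7.4. Among the 4 late samples, 20 min stood apart in the median of the glycerol genes (0.0793, others -0.26 to -0.21) and of the anaerobic genes (-0.0713, others 0.07 to 0.08). As deposited the glycerol genes stood at 0.73 at 20 min and 0.06 to 0.41 at the others, and the anaerobic genes at 0.02 and -0.17 to 0.14. Spots without a gene name entered no comparison, and 9 of 437 were at least 2-fold from before late (7 higher and 2 lower, the highest at 1.92), or 2.06% against 2.66% of genes, with 1 such spot at 0 against -10 min.

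The genes araE, araF, araG and araJ were already higher at 0 min, the sample labelled as the point of induction, than at -10 min. Their median over -10 min was 2.27 at 0 min, 1.03 at 2 min, 1.62 at 5 min, 2.25 at 10 min and 3.49 at 60 min. An error of the array of 0 over -10 min alone is argued against by the array of 2 over 0 min, where their median was -1.33, below the bound of -0.28 by more than the duplicate-spot SD of 0.24. An exchange with a later sample is argued against by the lowest later median, 1.03 at 2 min, only if the true 0 min sample stood at the -10 min level. If the response had begun by then, this test cannot decide. The list's percentile among lists matched on loop mean was 100, so it stayed high after the correction had removed the trend with loop mean. Dye bias that follows brightness cannot be decided, as signal intensities were not used. It stays open whether the response may have begun by the time the 0 min RNA was collected; no biological explanation was tested.

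Genes lower early or late crowd at the top edge of the slide. In the first row of the top print blocks 53.1% of spots (26 of 49) were at least 2-fold lower, against 1.06% (2 of 188) in the first rows of the other 3 rows of blocks (Fisher's exact test, p = 5.34e-19). That p describes the crowding that prompted the test and is no independent support. The first rows of those other blocks did not stand above their own remaining spots (1.06% against 1.09%, Fisher's exact test, p = 1), which argues against the part of the chromosome printed in first rows. An effect of the slide edge thus may account for these low values, and it covers secM, lpd, apaG, aroL, yadV, frmA and insL1 among the lowest late genes. No biological explanation was tested.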

How the results depend on the processing

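Chosen after seeing the data were the correction and its forms, the deposited values set beside corrected ones, the left-out slide edge, list tests on corrected values, all early list settings and the fit of time points as samples on corrected values. Centring, scaling, baselines, left-out times and the left-out closing array were planned, but for 2-fold counts and named genes they were run on corrected values (centring for counts only). The rest were planned. The loop test gave 0 genes in all comparisons under centring, scaling, robust empirical Bayes, 1 missing array allowed and the largest closures left out. It also gave 0 with either baseline, run for early and late against before, and with each left-out time, run for these 2 and for late against early. With time points as samples it gave 1 gene early as deposited, leuO, at -2.88 before the median of all genes was subtracted. On corrected values it gave 3 late (rplC, osmB and argA) and 1 late against early (osmB), in a fit that over-called in simulation. Genes at least 2-fold apart numbered 19 at 0 against -10 min (32 as deposited and 32 with loess alone) and 50 early. The early count was 523 as deposited, 103 with block medians, 178 with loess alone, 77 with loess within blocks, 25 without the outer spots, 87 against -10 min alone, and 24 to 158 with 1 time left out (without 5 and without 2 min). The 104 late became 603 as deposited, 214 with loess alone, 68 without the outer spots and 66 with scaled arrays (100 to 131 with 1 time left out). The 89 late against early became 213 as deposited, 201 with loess alone and 72 to 174 with 1 time left out (without 5 and without 10 min; 159 without 20 min). The 10 lists shifted late became 0 with an estimated correlation, as did the 11 on corrected values. Lists with the opposite direction and an adjusted p under the threshold were the aerobic respiratory chain (scaled 0.000747; corrected 0.00112, by rank 0.00128, block medians 0.0171, 2-spot window 0.000554, -10 min baseline 0.00677, 0 min baseline 0.000679, without 20, 30, 45 and 60 min 0.000239, 0.000437, 0.00188 and 0.0154), the TCA cycle (corrected 0.0290, 2-spot window 0.0264, 0 min baseline 0.0102, without 20 min 0.00268, without 30 min 0.0423), flagella (corrected 0.0290, by rank 0.0284, baselines 0.0371 and 0.0463, without 45 min 0.0134, without 60 min 0.0180), methionine (corrected 0.00994, by rank 0.0133, block medians 0.0266, 2-spot window 0.0132, baselines 0.0350 and 0.00763, without 20, 30, 45 and 60 min 0.0154, 0.0386, 0.000837 and 0.0314) and leucine, isoleucine and valine (scaled 0.0271). Early, against an upward median as deposited, the corrected test called sigma E (0.0113, 0 min baseline 6.58e-05, without 2 min 0.000575, without 5 min 0.0312) and Cpx (0.0250, -10 min baseline 0.0241, without 5 min 0.00311) downward. For all these the cause was not tested. Of 616 list results under alternatives, 71 lost and 20 gained a call in the same direction; 9 lists as deposited and 12 after correction lay outside the middle 95% of random lists. Of 84 counts by time 21 moved by over 1.5 times, and 261 of 2025 values of named genes moved by more than the SD between duplicate spots. Over 21 settings with the preset correlation, arabinose, ribosomal proteins and histidine were called the same way in 21, Cpx and arginine in 20 and Rcs in 18. After correction 10 to 12 lists passed with 1 late time left out. Of 205 values of named genes, 19 had the other sign as deposited, 2 with block medians, 1 with the 2-spot window and 1 without the closing array. The closing array was left out only after a correction that had used all 9 arrays. That correction brings each gene's 9 array values near a sum of 0, so the other arrays still carry the closing value. This setting is therefore no independent check. Readings in other log bases were not run, since the values are signed folds, and without the closing array only values by size exist. No paired analysis was possible because each time is 1 sample and no replicate numbers are shared. What signal over background limits is unknown here.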

Other observations

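The genes and courses in this and the next paragraph were chosen after their values were seen, as were the tests of loop mean for Cpx and Rcs and of slide position for Rcs; the other tests were set before their results were seen. Several genes of pyrimidine synthesis and salvage, for which no list was fixed and no test was run, stood low at 60 min. The aspartate carbamoyltransferase genes pyrB and pyrI stood at -3.58 and -2.55, the carbamoyl phosphate synthetase genes carA and carB at -3.06 (-2.32 as deposited) and -2.43, the cytosine deaminase gene codA at -2.09, codB of the same operon at -1.48 and pyrC at -1.42, against -0.65 for pyrD, -0.21 for pyrE and -0.08 for pyrF. Their courses differed. At 20 min pyrB, pyrI, codA and pyrD stood at 1.12, 1.00 (0.15 as deposited), 0.89 and 0.89, and carA, carB and pyrC at 0.43, 0.38 (1.38 as deposited) and 0.11 (1.22 as deposited). In contrast codB was already at -2.61 at 5 min and at -1.13 (-0.21 as deposited) at 20 min, and pyrE and pyrF stood at -0.40 (-1.80 as deposited) and -0.67 at 20 min. After correction pyrB, carA, pyrI and carB were at -1.68, -2.20, -1.31 and -1.98 on the array of 60 over 45 min. On that of -10 over 60 min they were at 3.51, 3.03, 2.33 and 2.39. The correction brings each gene's 9 array values near a sum of 0. The value on the closing array therefore nearly follows from the other arrays and is no separate check of the level. Both arrays hold the same 60 min RNA, so they do not show whether another sample would behave likewise. As carA and carB also belong to the arginine list, that list shares part of these low values.

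Galactose genes stood higher through the late times, with galK at 1.94, galP at 1.76, galT at 1.48 (2.08 as deposited) and galM at 1.45 at 60 min, against -0.44 for mglB. The 7 measured phage shock genes stood higher at 60 than at 20 min: pspA stood at -0.05 (1.15 as deposited) and 1.76, pspC at -1.10 and 1.11, pspG at -1.24 and 1.50 and pspE at -1.54 (-0.47 as deposited) and 0.64. The gene pspB stood at 0.86 (1.97 as deposited) and 2.34, pspD at -0.45 and 0.89, and pspF at 0.14 and 0.42. At the same 2 times dgcZ stood at 0.29 (1.16 as deposited) and 4.51, ycfJ at 1.21 (1.92 as deposited) and 4.04, yaiY at 0.22 and 3.74, yebE at 0.43 and 3.01, spy at 0.01 (-0.65 as deposited) and 2.17 and rcsA at -0.38 and 2.44. In contrast ivy stood at 2.07 and 1.88 (2.59 as deposited), and rpoE at -1.64 at 10 min, -1.19 at 20 min and 0.00 at 60 min. These are values from 1 culture with no test.

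Cpx and Rcs genes were higher late, and 3 technical explanations were weighed. Dye bias that follows brightness cannot be decided, since signal intensities were not used and the correction had already removed the trend with loop mean. The lists stayed high after that step: the lower of the 2 lists' percentiles among lists matched on loop mean was 99.1. Slide position is argued against for Rcs, whose median was 0.40 with the outer spots left out and a narrower window. For Cpx, whose median over the 13 members left was -0.0272, it stays open. That test dropped members and narrowed the window at once, so it cannot tell what lowered the median. The crowding at the top edge was of low values, with 26 of 49 first-row spots lower and 0 higher. A single late sample stays open for Cpx too, with a median of 0.0617 without 60 min and a bootstrap SE of 0.20, so that this and a true shift of the list cannot be told apart. Envelope stress from the release protein may be a biological explanation, and it was not tested, since no culture without induction or with another protein was analysed here.

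In the comparison of late with early times, chance could not be excluded for the number of genes at least 2-fold apart. Of the 35 splits of the 7 samples into 3 and 4, 4 gave at least the real 89, the real split included. The highest other split, 30, 45 and 60 min against the rest, gave 121, 5, 10 and 20 min against the rest gave 109, and 2, 45 and 60 min against the rest, which mixes the first and the last times, gave 93. Splits that group adjoining times also follow the time course, so this test cannot tell chance from a gradual change. The loop test gave 0 genes in the real split and at most 0 in the others (35 of 35), and as it also called 0 of the 200 simulated changes, it says nothing about the grouping.

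If the late differences were measurement noise alone, genes next to each other on the chromosome would be no more alike than genes farther apart. Across 3406 neighbouring pairs the late differences correlated at r = 0.16, against at most 0.07 for genes 2 to 10 places apart and 0.06 for genes 11 to 30 places apart, so noise alone is argued against; genes are not independent replicates. For late against early the values were 0.21, 0.08 and 0.06, and for 0 against -10 min 0.09, 0.05 and 0.03. Early against before they were 0.06, 0.10 and 0.06, so neighbours lay below the value at 4 genes apart and close to the highest at 11 to 30. The spots follow the order of the chromosome: 2420 of 3321 neighbouring pairs with 1 spot each lie at the same place of adjoining print blocks. Among these, the 1127 pairs with at most 50 bases between the genes correlated late at r = 0.27 and the 1293 pairs farther apart at 0.10, a difference of 0.17 with a bootstrap SE of 0.04. For late against early the difference was 0.25 (bootstrap SE 0.04), but early against before it was 0.03 (0.04) and for 0 against -10 min -0.05 (0.07). For the late changes this argues against the print layout as the whole source, since the layout does not follow the distance between genes. Part of the likeness may still come from it. For early against before and 0 against -10 min the print layout stays open. A candidate explanation is that genes of one operon share their changes.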
